A study of Homo sapiens with 38 samples.

How the data were processed

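Total RNA from 38 cultures was labelled as biotinylated cRNA and hybridized by the submitters to Affymetrix U133 Plus 2.0 arrays, 1 array per culture without pooling. The deposited values are MAS5 signals on a linear intensity scale, per the labels and the submitters' processing notes. Tested on the file, the 2% trimmed mean of the 100 normalization probe sets of the platform was equal within 0.02 on all arrays of 1 line and mtDNA status and differed between the 4 lines, while the trimmed mean of all probe sets differed between arrays. The deposited table holds 54675 probe sets, 232 of them with a missing value on up to 11 arrays. The doses of 2DG and TM are not given here.

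Each array was scaled to a common 2% trimmed mean of 114 over all probe sets, and the log2 of the scaled signal plus 5% of that trimmed mean was used. Of the probe sets, 41097 carry 1 gene symbol, 1801 several and 11777 none, and only the first kind was used. A probe set entered if at least 2 arrays reached 40% of the trimmed mean, which 21477 did. The probe set with the highest mean over the 38 arrays stood for its gene, giving 11457 genes. Probe sets without a symbol and detection calls were not used here.

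Genes were tested with limma 3.58.1 in R 4.3.3, with an intensity trend in the empirical Bayes step and Benjamini-Hochberg adjusted p under 0.05. The sample descriptions name 1 control array for each treated array, and each such set was a fixed block, so that each treated array was compared with its own control. A first fit had a coefficient per group (5 residual degrees of freedom). A fit by class gave the 5 respiratory inhibitors with 2DG 1 shared coefficient. GS with Rot and GS with AA (including floating cells) had another, and TM with Rot and TM with AA another (11 residual degrees of freedom). The spread between compounds thus counts as error. The 12 controls were compared in a fit without a block (8 residual degrees of freedom). Groups with 1 array were assumed to vary like the replicated groups. In the first fit the spread comes only from HT-1080 2DG, HT-1080 GS and HT-29 GS, and is shared by both lines. The HT-29 GS group holds the 14 h array, so its spread includes that difference in time. The p-values measure only the spread between these cultures. Changes are log2 differences, and SE is the limma standard error of a log2 change.

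The 15 gene lists, 2 marker lists, comparisons, alternatives and the rule for naming genes were fixed in advance. The lists covered ER chaperones and ERAD, the ATF4 stress response, aminoacyl-tRNA synthetases, glycolysis, hypoxia, oxidative phosphorylation, mtDNA-encoded transcripts, cell cycle, cholesterol synthesis, cytosolic heat shock, mitochondrial chaperones, NRF2, p53, MondoA glucose sensors, and autophagy and lysosome. The marker lists were mesenchymal and colon epithelial. In each comparison the genes open to naming began with 11 stress genes fixed in advance. To these came the 8 largest rises and 8 largest falls among genes past the threshold that moved the same way on every treated array. Up to 4 members per list past the threshold were added (otherwise up to 2 given as values). The text gives only some of them in each comparison. Lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 17 lists in a comparison. Of the list calls given below with camera, only the fall of mtDNA-encoded transcripts in the rho0 controls also passed with an estimated correlation. A list score is the median log2 difference of an array from its own control over the list, and the scores of 5 arrays with inhibitors and 3 with 2DG alone were compared by an exact two-sided permutation test. Met, Bu and Phen share control 3, and Rot, AA and 2DG replicate 2 share control 4, which that test ignores.

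The fits were tested on simulated data with the same design, in which 100 of 11457 genes were given a log2 change of 1 and as many a change of 2. For 2DG 75% and 99% of them were recovered, for GS 45% and 96%, for HT-29 GS 60% and 99%, for TM 31% and 77%, for the inhibitors with 2DG 55% and 93%, for GS with VST 59% and 96%, for 2DG with VST 9% and 61%, for the inhibitor effect under 2DG less that under TM 20% and 67%, and for the rho0 controls 65% and 96%. Alternatives tried were other offsets, no filter and a stricter one, quantile normalization, the mean of all probe sets of a gene, no intensity trend, no replicate block, arrays of the same line only, subsets of the inhibitors, and leaving out each array. The deposited scaling and the removal of arrays with a high ACTB ratio were added after seeing the data. Control groups of 6 arrays were searched for single arrays far from the others with Dixon's test. The 2 spike-in control classes of the array were used only as a check.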

Results

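Gene expression was measured on 38 Affymetrix U133 Plus 2.0 arrays from human tumour cell lines, 1 array per culture. HT-1080 is a fibrosarcoma line, HT-29 is a colorectal adenocarcinoma line, and rho0 names derivatives of each that lack mitochondrial DNA (mtDNA). Of the 38 arrays, 12 were controls: 6 of HT-1080, 2 of HT-1080 rho0, 3 of HT-29 and 1 of HT-29 rho0. The other 26 came from cells under 1 of 3 stresses. 2-Deoxyglucose (2DG) is a glucose analogue that blocks glycolysis and protein glycosylation, glucose starvation (GS) removes the sugar, and tunicamycin (TM) blocks N-glycosylation in the endoplasmic reticulum (ER). HT-1080 had 3 arrays with 2DG, 2 with GS and 1 with TM, and HT-29 had 3 with GS. Every other treatment had 1 array and so no replicate.

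The added compounds were rotenone (Rot, 100 nM), which inhibits complex I of the respiratory chain, antimycin A (AA, 10 ng/ml), which inhibits complex III, and the biguanides metformin (Met, 10 mM), buformin (Bu, 300 µM) and phenformin (Phen, 100 µM), which inhibit complex I more weakly. Versipelostatin (VST, 3 µM) is a macrocyclic compound that blocks induction of ER chaperones in cells short of glucose. Treatment lasted 18 h, except 14 h for HT-29 GS replicate 3 and HT-29 rho0 GS. Arrays marked S include the floating cells of the culture. No array had a compound without a stress, so the effect of a compound by itself cannot be separated from a changed stress response. The series asks how mitochondrial function shapes the unfolded protein response (UPR), the programme that raises ER folding capacity when unfolded proteins accumulate, in cells under these stresses.

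The number of arrays limits the precision of every value. The array-wide signal, as the 2% trimmed mean of the deposited intensities, was 124 to 136 on the parental controls and 122 to 131 on the 9 parental arrays with 2DG, GS or TM alone. It was 89.2 to 102 on the 11 arrays of 2DG or GS with a compound and 90.0 to 96.3 on the 3 rho0 arrays with 2DG or GS. With TM the compounds left it at 118 to 119. The deposited values were equal in the 100 normalization probe sets within each line and mtDNA status, so this signal is relative to those. All values below come after scaling every array to the same trimmed mean. GAPDH and ACTB, abundant housekeeping transcripts with probe sets at both ends, gave 3' to 5' signal ratios of 0.913 to 1.07 and 1.04 to 1.76. Most line markers separated the lines: EPCAM, an epithelial adhesion protein, had a mean signal of 5380 on the 9 HT-29 arrays and 5.02 on the 29 HT-1080 arrays, and SPARC, a matrix protein of mesenchymal cells, had 1.30 and 2094. Of the 10 mesenchymal markers 2 went the other way, with HT-29 and HT-1080 means of 7837 and 32.4 for S100A4 and 111 and 10.3 for TAGLN.

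**Figure D1:**
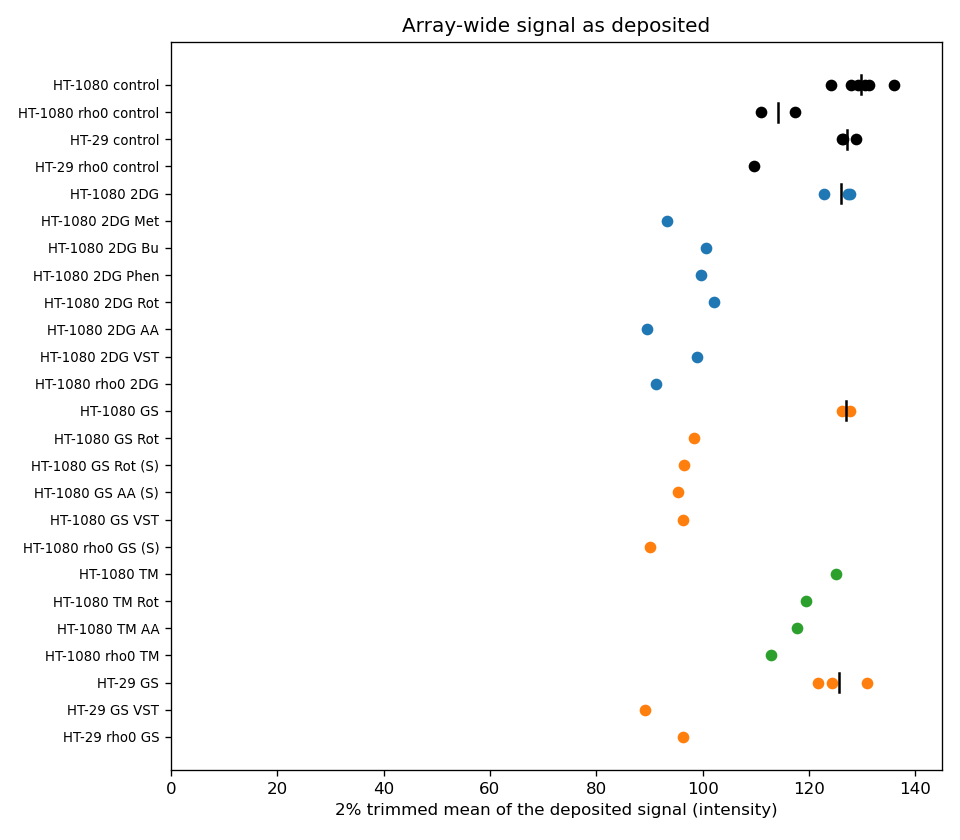
Each point is 1 array; the horizontal axis is the 2% trimmed mean of the deposited signal (intensity) and vertical bars are group means. Arrays of 2DG or GS with a compound lie between 89.2 and 102, below the parental controls at 124 to 136.

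The first comparison asks what 2DG does to HT-1080 cells, with 3 treated arrays each against its own control. 2DG raised the ER folding machinery. HSPA5, the main ER chaperone and sensor of unfolded protein, rose by 1.30 (SE 0.12, adjusted p = 0.000425), and HSP90B1, an ER-resident HSP90, rose by 2.09 (SE 0.18, adjusted p = 0.000209). HERPUD1, a scaffold of ER-associated degradation (ERAD), rose by 1.93 (SE 0.27, adjusted p = 0.00268). A second group was the amino acid response controlled by ATF4: ASNS, which makes asparagine, rose by 2.93 (SE 0.24, adjusted p = 0.000206), SLC3A2, a subunit of amino acid exchangers, rose by 3.39 (SE 0.22, adjusted p = 6.15e-05), and INHBE, a secreted activin subunit, rose by 3.69 (SE 0.60, adjusted p = 0.00491). DDIT3, the stress transcription factor CHOP, rose by 2.73 (SE 0.53, adjusted p = 0.0111), whereas ATF3, a related factor, did not pass the threshold (log2 change 1.18, SE 0.49, adjusted p = 0.160).

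In all, 555 of 11457 genes rose and 395 fell under 2DG. In the ER chaperone and ERAD list, 25 of 33 measured members rose and 0 fell, or 32 and 0 adjusted over the list alone. The median log2 change was 1.29 (camera adjusted p = 2.09e-21, and adjusted p = 0.298 with an estimated correlation). In the ATF4 list, 20 of 30 measured members rose and 0 fell, or 28 and 0 adjusted over the list alone. Its median moved by 1.31 on the log2 scale (camera adjusted p = 6.03e-17, and adjusted p = 0.298 with an estimated correlation). Among the aminoacyl-tRNA synthetases, which load tRNAs, 10 of 17 measured members rose and 0 fell, or 10 and 1 adjusted over the list alone, with WARS1 and SARS1 up by 1.74 and 1.23. The list median was 0.42 (camera adjusted p = 7.03e-05, and adjusted p = 0.298 with an estimated correlation). TXNIP, a brake on glucose uptake that responds to sugar phosphates, rose by 3.30 (SE 0.24, adjusted p = 7.62e-05), and ARRDC4, its relative, rose by 2.05 (SE 0.38, adjusted p = 0.00900). Proliferation genes moved down: in the cell cycle list, 0 of 33 measured members rose and 17 fell, or 0 and 22 adjusted over the list alone, with the mitotic kinase PLK1 at -1.31. Over the whole list the median log2 change was -0.67 (camera adjusted p = 1.62e-13, and adjusted p = 0.347 with an estimated correlation). Of 45 nuclear-encoded respiratory chain genes 5 fell, among them NDUFV2 of complex I (-0.67). IFIT1, an interferon-induced antiviral gene, fell by 2.12 (SE 0.33, adjusted p = 0.00406), and ID1, an inhibitor of differentiation factors, fell by 1.87 (SE 0.39, adjusted p = 0.0146). Without 2DG replicate 1, 2 or 3 the count went from 950 to 98, 92 and 203, and without their controls to 98, 93 and 199. With the block, a treated array without its control has no reference, so leaving out either is the same check. The same holds below for GS in both lines and for the line difference.

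Glucose starvation of HT-1080 asks whether removing the sugar gives the same programme (2 treated arrays, each with its control). It raised the ER genes again: HSPA5 rose 2.64-fold (adjusted p = 0.00234), and CRELD2, a secreted ER stress marker, rose by 2.82 (SE 0.32, adjusted p = 0.00234). HSPA6, a strictly inducible cytosolic HSP70, rose by 5.75 (SE 1.12, adjusted p = 0.0119), HMOX1, which degrades haem, rose by 5.33 (SE 0.76, adjusted p = 0.00356), and the immediate-early factor EGR1 rose by 5.47 (SE 0.62, adjusted p = 0.00234). TXNIP, which rose with 2DG, did not pass the threshold (log2 change -0.48, SE 0.29, adjusted p = 0.334), and its response was lower with GS than with 2DG (difference -3.77, adjusted p = 0.00497).

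Under GS 487 genes rose and 589 fell. In the ER list, 22 of 33 measured members rose and 0 fell, or 32 and 0 adjusted over the list alone. These genes had a median log2 change of 1.29 (camera adjusted p = 1.12e-19, and adjusted p = 0.284 with an estimated correlation). Of the ATF4 list genes, 17 of 30 measured members rose and 0 fell, or 25 and 0 adjusted over the list alone. On the log2 scale the median change was 1.42 (camera adjusted p = 4.46e-15, and adjusted p = 0.284 with an estimated correlation). The ATF4 scores of the 2 GS arrays, each the list median against its own control, were 1.94 and 0.47, the second against control 6, which had the highest ATF4 list signal of the 6 controls. Starved cells lowered proliferation and sterol genes. In the cell cycle list, 0 of 33 measured members rose and 22 fell, or 0 and 32 adjusted over the list alone, with E2F1, which starts DNA synthesis, at -1.73 and PCNA, the replication clamp, at -1.54. For this list the median log2 change was -1.13 (camera adjusted p = 1.39e-15, and adjusted p = 0.284 with an estimated correlation). In the cholesterol synthesis list, 0 of 16 measured members rose and 9 fell, or 0 and 12 adjusted over the list alone, with the sterol sensor INSIG1 at -1.53. The members had a median log2 change of -0.91 (camera adjusted p = 1.82e-07, and adjusted p = 0.284 with an estimated correlation). Of 15 antioxidant genes in the NRF2 list 6 rose, or 7 adjusted over the list alone, among them GCLC (1.21). The median log2 change was 0.64 (camera adjusted p = 8.71e-05, and adjusted p = 0.478 with an estimated correlation). Of the 555 genes that rose with 2DG, 252 also rose with GS, where independent lists would share 23.6, and of the 395 that fell 181 also fell, against 20.3. The effect sizes of these 2 comparisons share no arrays. Their calls share 1 estimate of the spread per gene, so they are not independent, and 23.6 and 20.3 may be too low a reference. A direct test of GS against 2DG left 1 gene higher and 1, TXNIP, lower in limma, with 881 at an unadjusted p under 0.05. Without GS replicate 1 or its control the GS count was 20, and without replicate 2 or its control 47.

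HT-29 cells answer whether another tumour line responds alike (3 GS arrays, 3 controls). In starved HT-29 cells ATF3 rose by 6.08 (SE 0.49, adjusted p = 0.000114), DDIT3 rose by 5.62 (SE 0.53, adjusted p = 0.000209), and PPP1R15A, a phosphatase subunit that restarts translation after stress, rose by 4.26 (SE 0.27, adjusted p = 2.05e-05). HSPA5 rose by 1.13 (SE 0.12, adjusted p = 0.000381) and HERPUD1 rose by 2.75 (SE 0.27, adjusted p = 0.000245). AXIN2, a feedback inhibitor of Wnt signalling, and the stem cell receptor LGR5 fell, at -2.61 and -2.40. VEGFA, the angiogenic growth factor, rose by 2.44 and was 1 of 7 members of the hypoxia list that rose. Adjusted over the list alone 7 rose and 1 fell. Its median moved by 0.27 on the log2 scale (camera adjusted p = 0.00513, and adjusted p = 0.610 with an estimated correlation).

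In HT-29 1322 genes rose and 1784 fell. The spread behind these counts is shared by both lines. With arrays of the same line only, GS changed 1159 genes in HT-29 and 2804 in HT-1080, so the counts do not rank the lines. Of the ER genes, 28 of 33 measured members rose and 0 fell, or 29 and 0 adjusted over the list alone. The list median was 1.13 (camera adjusted p = 1.89e-15, and adjusted p = 0.586 with an estimated correlation). For the ATF4 list, 27 of 30 measured members rose and 1 fell, or 27 and 2 adjusted over the list alone. Over the whole list the median log2 change was 1.76 (camera adjusted p = 1.89e-15, and adjusted p = 0.586 with an estimated correlation). The cell cycle list moved down: 1 of 33 measured members rose and 27 fell, or 1 and 30 adjusted over the list alone. These genes had a median log2 change of -1.03 (camera adjusted p = 8.05e-10, and adjusted p = 0.606 with an estimated correlation). The p53 list went both ways, with 4 members up and 3 down both over all genes and adjusted over the list alone: CDKN1A, which stops the cell cycle, rose by 3.48 and GADD45A, a DNA damage gene, by 3.05, while its median was -0.07 and its mean 0.57. The GS effect differed between the lines for 65 genes, 19 higher in HT-1080 and 46 higher in HT-29. Picked after their values were seen, DUSP1, which dephosphorylates MAP kinases, differed by -4.54 (adjusted p = 0.0241) and CDKN1A by -3.71 (adjusted p = 0.0264), HT-1080 minus HT-29. Replicate 3, the 14 h culture, had an ER score of 0.38 beside 1.27 and 1.53. The HT-29 count was 1190 without replicate 1 or 1547 without replicate 2 (1184 and 1530 without their controls), and the count of genes that differed between lines was 766 without HT-29 replicate 3, 7 without HT-1080 replicate 1 and 0 without HT-1080 replicate 2, with 763, 7 and 0 without their controls.

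**Figure D2:**
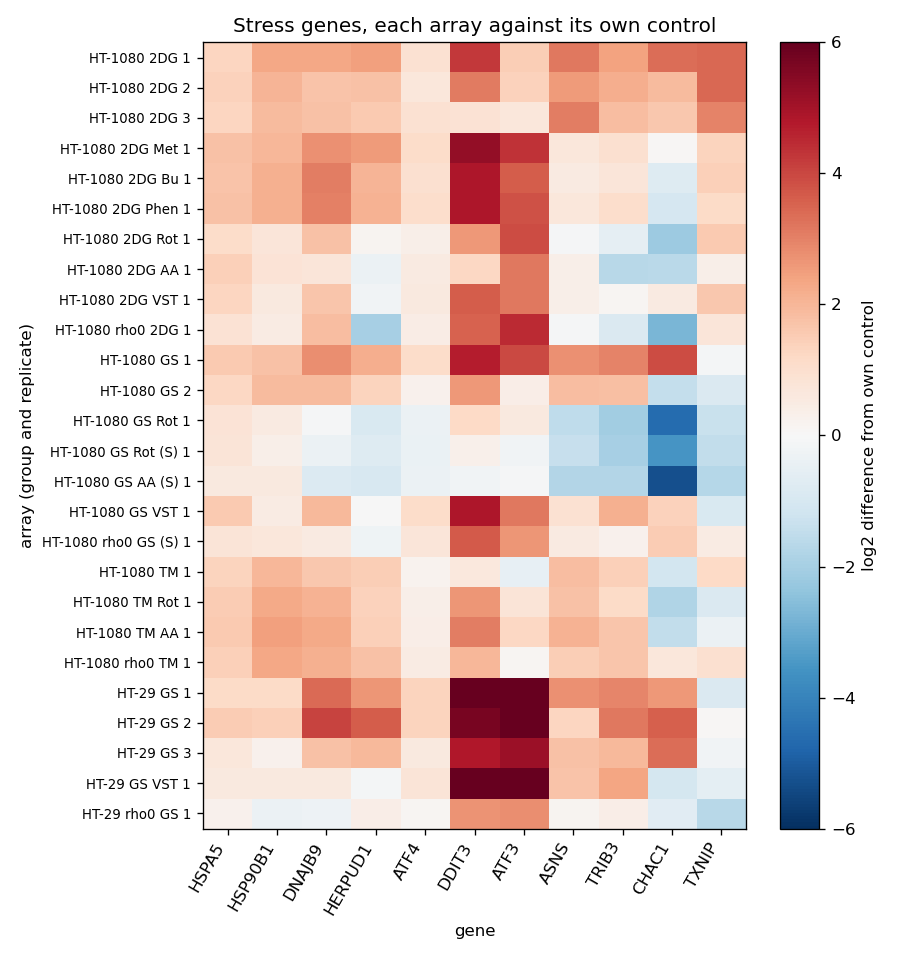
Colour is the log2 difference of each treated array (rows: group and replicate) from its own control for 11 stress genes (columns). S marks arrays that include floating cells. After the common scaling HSPA5 lies above control on all 26 treated arrays, while ASNS and TRIB3 lie above it on the parental arrays of 2DG, GS or TM alone and below it on the GS arrays with rotenone or antimycin A.

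Respiratory inhibitors with 2DG ask how expression under 2DG changes when the respiratory chain is inhibited (5 arrays, with Met, Bu, Phen, Rot or AA, against 3 with 2DG alone). ASNS fell by 2.51 (SE 0.24, adjusted p = 3.29e-06), TRIB3, a pseudokinase induced by ATF4, fell by 2.57 (SE 0.41, adjusted p = 0.000156), and CHAC1, which degrades glutathione, fell by 3.60 (SE 0.71, adjusted p = 0.000833); each was lower on 5 of 5 arrays. HSPA5 did not pass the threshold (log2 change 0.10, SE 0.15, adjusted p = 0.638) on its most abundant probe set, and another, weaker probe set of HSPA5 gave -1.62. HSP90B1 fell by 0.87 (SE 0.25, adjusted p = 0.0106) and was lower on 3 of 5 arrays. ATF3 went the other way and rose by 2.42 (SE 0.50, adjusted p = 0.00110), as did the growth regulator MYC, which rose by 3.18 (SE 0.29, adjusted p = 1.90e-06). DDIT3 lay 4.85 to 5.29 above the own control with the biguanides, 2.58 with Rot and 1.24 with AA, beside 0.85 to 4.22 with 2DG alone. DNAJB9, an ER co-chaperone, lay 2.75 to 3.06, 1.76 and 0.73 above it, beside 1.72 to 2.32 with 2DG alone.

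With the inhibitors 1457 genes rose and 2472 fell against 2DG alone (357 and 4627 with the deposited scaling). The median of all genes was -0.12 after the common scaling and -0.48 with the deposited one. Among ATF4 list genes, 3 of 30 measured members rose and 17 fell, or 3 and 18 adjusted over the list alone. On the log2 scale the median change was -1.17 (camera adjusted p = 0.000484, and adjusted p = 0.426 with an estimated correlation), and -1.52 with the deposited scaling. For the ER list, 0 of 33 measured members rose and 19 fell, or 0 and 19 adjusted over the list alone, with SEL1L, an ERAD adaptor, at -1.88 and CRELD2 at -1.95. For this list the median log2 change was -0.65 (camera adjusted p = 0.000484, and adjusted p = 0.508 with an estimated correlation), and -1.04 with the deposited scaling. With the 3 biguanides alone the ER median was -0.14 (camera adjusted p = 0.568) and the ATF4 median -0.84 (adjusted p = 0.144). In the oxidative phosphorylation list, 34 of 45 measured members rose and 0 fell, or 36 and 0 adjusted over the list alone. The members had a median log2 change of 0.52 (camera adjusted p = 1.08e-12, and adjusted p = 0.426 with an estimated correlation), and 0.14 with the deposited scaling. Ribosomal protein genes, looked up after this result was seen, moved nearly as much: 49 of 51 rose, with a median of 0.47 (0.08 with the deposited scaling, 0.01 with quantile normalization and 0.44 for random lists matched on expression). The rise was therefore not particular to the respiratory chain. Of the cell cycle genes, 18 of 33 measured members rose and 0 fell, or 19 and 0 adjusted over the list alone, led by RRM2, which makes deoxynucleotides (1.42). The median log2 change was 0.68 (camera adjusted p = 2.54e-07, and adjusted p = 0.426 with an estimated correlation), and 0.30 with the deposited scaling. Of 12 heat shock genes 6 rose, or 7 adjusted over the list alone, with DNAJB1, an HSP70 co-chaperone (2.27). Its median moved by 0.56 on the log2 scale (camera adjusted p = 0.00213, and adjusted p = 0.426 with an estimated correlation), and 0.24 with the deposited scaling. The basement membrane collagens COL4A1 and COL4A2 fell, at -2.64 and -2.15. VMP1, an autophagy protein, rose by 3.73 (SE 0.27, adjusted p = 3.55e-07). Without 2DG replicate 2 the count was 1870.

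Per array, the ATF4 list scored 0.29 ± 0.26 (SD, n = 5) with the inhibitors and 1.27 ± 0.09 (SD, n = 3) with 2DG alone, a difference of -0.98 (exact two-sided permutation p = 0.0179, the smallest that 56 splits allow; adjusted over 17 lists 0.0379). In all 8 of the 17 lists reached this p: besides ATF4, oxidative phosphorylation, cell cycle, cytosolic heat shock, mitochondrial chaperones, p53, autophagy and lysosome, and the colon epithelial markers, so the difference was not specific to ATF4. With quantile normalization ATF4 differed by -1.03 (exact permutation p = 0.0179), and no list passed after adjustment (ATF4 0.0506). There cell cycle, p53, and autophagy and lysosome kept 0.0179, and heat shock and the colon markers had 0.0357. Oxidative phosphorylation had 0.0536, and the mitochondrial chaperones differed by -0.07 (exact permutation p = 0.411). Several arrays come from the same control set, which this test ignores, also where the mean of all 6 controls was used (ATF4 difference -0.91, exact permutation p = 0.0179, adjusted 0.0337). The ER list scored 0.66 ± 0.36 and 1.18 ± 0.08, a difference of -0.52 (exact permutation p = 0.0714, adjusted 0.0934), which did not pass. The biguanide arrays had ER scores of 0.76 (Met), 1.02 (Bu) and 0.96 (Phen), and the arrays with Rot and AA had 0.37 and 0.20, the AA score becoming -0.31 with the deposited scaling. HERPUD1 lay 2.05 to 2.57 above control with the biguanides, 0.16 with Rot and -0.37 with AA. Between the biguanides and Rot with AA no ER list gene passed over all genes and 7 were higher adjusted over the list alone. Over all genes limma called 0 higher and 1 lower, with 941 at an unadjusted p under 0.05. Between the 3 biguanides the threshold was passed by 5 genes for Met against Bu, 1 for Met against Phen and 1 for Bu against Phen, with 1 array per compound. These counts depend on the scaling: they were 41, 40 and 5 with quantile normalization and 6, 0 and 0 with the deposited scaling (limma, 1026 and 398 at an unadjusted p under 0.05 for the last 2). Named after their values were seen, these include NORAD, a noncoding RNA that was lower with Met than with Bu (log2 change -1.80, adjusted p = 0.0192), and ATPSCKMT, a mitochondrial methyltransferase that was higher (log2 change 2.60, adjusted p = 0.0192).

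**Figure D3:**
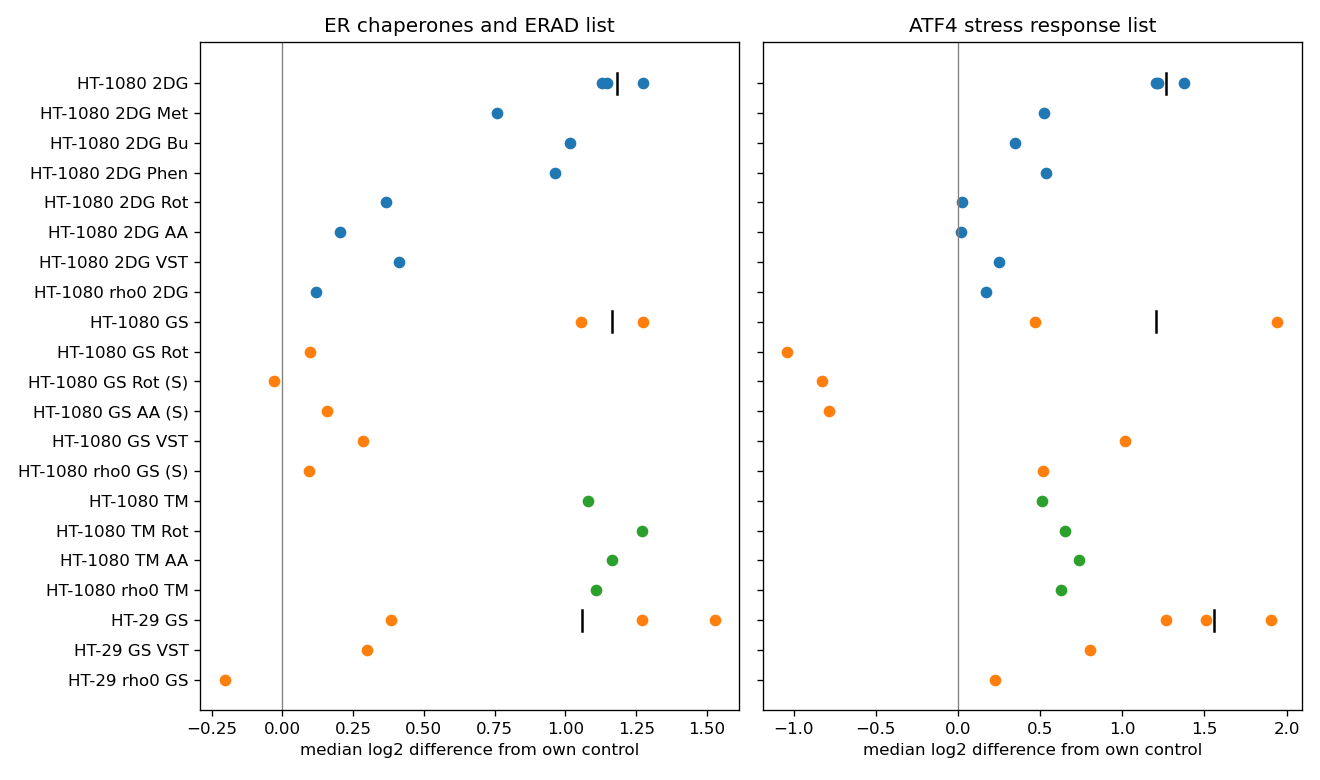
Each point is 1 array; the horizontal axis is the median log2 difference from its own control over the ER list (left) or the ATF4 list (right), and vertical bars are means of replicated groups. ER scores are 1.13 to 1.28 with 2DG alone, 0.20 with 2DG and antimycin A (-0.31 with the deposited scaling), and 1.08 to 1.27 on the HT-1080 arrays with TM, with or without rotenone or antimycin A.

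The same question was asked under glucose starvation, with 1 array each of Rot and of AA (including floating cells) against 2 GS arrays. ER and amino acid stress genes were lower. HSPA5 fell by 0.63 (SE 0.18, adjusted p = 0.0152), DNAJB9, an ER co-chaperone, fell by 2.57 (SE 0.51, adjusted p = 0.00129), DDIT3 fell by 2.63 (SE 0.87, adjusted p = 0.0336), ASNS fell by 3.74 (SE 0.29, adjusted p = 6.43e-07) and TRIB3 fell by 4.04 (SE 0.49, adjusted p = 2.80e-05). Control 6, which these arrays share with GS replicate 2, had the highest signal of the 6 HT-1080 controls for ASNS, TRIB3 and DDIT3 and the highest ATF4 list median (8.51 on the log2 scale, the others 7.46 to 7.88). RNA quality also moved with the treatment: ACTB 3' to 5' ratios were 1.51 with Rot and 1.76 with AA, beside 1.26 and 1.42 with GS alone, and polyA to hybridization control ratios were 1.93 and 2.20 times those of the own control, less than the 2.33 by which 2 controls of 1 line differed. The part of RNA quality in these changes cannot be separated here. HMOX1 fell by 4.11 (SE 0.71, adjusted p = 0.000472). TAF1D, a subunit of the RNA polymerase I factor SL1 whose introns hold small nucleolar RNAs, rose by 4.69 (SE 0.37, adjusted p = 6.43e-07), and ID3 rose by 4.68 (SE 0.93, adjusted p = 0.00127).

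In this comparison 1295 genes rose and 1525 fell (569 and 3192 with the deposited scaling). Among ER list genes, 0 of 33 measured members rose and 25 fell, or 0 and 27 adjusted over the list alone. The list median was -1.11 (camera adjusted p = 8.33e-11, and adjusted p = 0.317 with an estimated correlation), and -1.49 with the deposited scaling. In the ATF4 list, 0 of 30 measured members rose and 25 fell, or 0 and 25 adjusted over the list alone. Over the whole list the median log2 change was -1.80 (camera adjusted p = 8.11e-13, and adjusted p = 0.256 with an estimated correlation), and -2.17 with the deposited scaling. Of 17 aminoacyl-tRNA synthetases 1 rose and 10 fell, or 2 and 10 adjusted over the list alone. These genes had a median log2 change of -0.58 (camera adjusted p = 0.000234, and adjusted p = 0.317 with an estimated correlation), and -0.96 with the deposited scaling. Proliferation and sterol genes were higher. For cell cycle genes, 23 of 33 measured members rose and 0 fell, or 28 and 0 adjusted over the list alone, with MKI67, a proliferation marker, at 1.79. On the log2 scale the median change was 1.07 (camera adjusted p = 6.56e-12, and adjusted p = 0.317 with an estimated correlation), and 0.69 with the deposited scaling. In the cholesterol list, 9 of 16 measured members rose and 1 fell, or 9 and 1 adjusted over the list alone, with HMGCS1, an early enzyme of sterol synthesis, at 2.26. For this list the median log2 change was 0.71 (camera adjusted p = 0.000453, and adjusted p = 0.317 with an estimated correlation), and 0.33 with the deposited scaling. Of 45 respiratory chain genes 27 rose, or 31 adjusted over the list alone. The members had a median log2 change of 0.53 (camera adjusted p = 1.98e-11, and adjusted p = 0.317 with an estimated correlation), and 0.14 with the deposited scaling. Of the ribosomal protein genes 47 of 51 rose, with a median of 0.54 (0.16 with the deposited scaling, 0.05 with quantile normalization and 0.35 for random lists matched on expression), so this rise too was not particular to the respiratory chain. Of 7 mtDNA-encoded transcripts 1 rose and 3 fell, the same adjusted over the list alone, with COX2 and COX3 of complex IV among the latter (-1.43 and -1.77). The median log2 change was -0.68 (camera adjusted p = 0.195, and adjusted p = 0.558 with an estimated correlation), and -1.06 with the deposited scaling. Of the 555 genes that rose with 2DG, 306 fell in this comparison, against 73.9 for independent lists. The effect sizes here use none of the 2DG arrays, but the estimate of the spread does. The calls are therefore not independent, and 73.9 may be too low a reference. Between the GS arrays with Rot taken with and without floating cells 0 genes changed in limma, with 279 at an unadjusted p under 0.05. The count was 217 without GS replicate 2, whose control Rot and AA share, and 1671 without the AA array.

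Tunicamycin tests whether the inhibitors act on ER stress as such (1 TM array, 1 with Rot and 1 with AA, all set against control 6). With TM the ER genes stayed high. HSP90B1 lay 2.00 above control with TM, 2.25 with Rot added and 2.47 with AA added, and ASNS lay 1.83, 1.78 and 2.09 above it. TM alone gave 0 genes past the threshold in limma and 687 at an unadjusted p under 0.05. Of the ER list 0 of 33 members passed over all genes and 21 rose adjusted over the list alone. Its median moved by 1.05 on the log2 scale (camera adjusted p = 1.30e-28, and adjusted p = 0.283 with an estimated correlation). In the ATF4 list 0 of 30 passed and 7 rose adjusted over the list alone. The list median was 0.80 (camera adjusted p = 2.03e-11, and adjusted p = 0.283 with an estimated correlation). Adding Rot or AA raised 15 genes and lowered 47; no ER list member and no ATF4 list member was among them. Adjusted over the list alone 0 ER genes changed, while 2 ATF4 genes rose and 1 fell. The ER median was 0.13 (camera adjusted p = 0.248, and adjusted p = 0.860 with an estimated correlation).

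The inhibitor effect itself differed between 2DG and TM. With 2DG it averages Met, Bu, Phen, Rot and AA, and with TM only Rot and AA. The contrast therefore mixes a difference between stresses with one between compounds. SLC7A11, the cystine importer, differed by -3.01 (adjusted p = 0.00203), ASNS by -2.62 (adjusted p = 0.00567) and PDIA4, an ER disulfide isomerase, by -1.84 (adjusted p = 0.0111). HSPA5, on its most abundant probe set, did not pass the threshold (log2 change -0.11, SE 0.25, adjusted p = 0.843). The difference passed for 520 genes, 189 higher and 331 lower under 2DG (57 and 933 with the deposited scaling). The median of all genes was -0.12. RNA quality moved on the TM side: against their own control, ACTB ratios were 1.03 times as high with TM, 1.13 with Rot added and 1.20 with AA added, beside 1.05 to 1.08 with 2DG and 1.00 to 1.15 with the inhibitors. PolyA to hybridization control ratios were 1.18, 1.38 and 1.70 times the own control on the 3 TM arrays. Without the arrays of high ACTB ratio, both TM arrays with an inhibitor among them, this contrast has no value. In the ER list, 0 of 33 measured members rose and 6 fell, or 0 and 16 adjusted over the list alone. Over the whole list the median log2 change was -0.91 (camera adjusted p = 3.68e-06, and adjusted p = 0.457 with an estimated correlation), and -1.22 with the deposited scaling. Of the ATF4 list genes, 0 of 30 measured members rose and 8 fell, or 0 and 11 adjusted over the list alone. These genes had a median log2 change of -1.26 (camera adjusted p = 1.16e-06, and adjusted p = 0.249 with an estimated correlation), and -1.52 with the deposited scaling. In the cell cycle list, 8 of 33 measured members rose and 0 fell, or 15 and 0 adjusted over the list alone, with E2F1 at 2.73. On the log2 scale the median change was 1.06 (camera adjusted p = 1.13e-11, and adjusted p = 0.250 with an estimated correlation), and 0.76 with the deposited scaling. The same difference for GS against TM passed for 1297 genes, 648 higher and 649 lower under GS (337 and 1276 with the deposited scaling). This count for 2DG less TM was 35 without TM with AA, 211, 43 and 292 without 2DG replicate 1, 2 or 3, and 212, 217 and 296 without HT-1080 control 2, 3 or 5.

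Versipelostatin was compared with GS alone in both lines (1 VST array per line, mean of both lines) and with 2DG alone in HT-1080 (1 array). HERPUD1 fell by 2.41 (SE 0.30, adjusted p = 0.000167), SEL1L fell by 3.04 (SE 0.33, adjusted p = 7.54e-05), and SDF2L1, an ER folding factor, fell by 2.30 (SE 0.23, adjusted p = 3.84e-05). HSPA5, on its most abundant probe set, changed by -0.22 (SE 0.14) and DDIT3 by 0.69 (SE 0.60), neither past the threshold. The HSPA5 value averages lines that differed. In HT-1080 it lay 1.58 above the own control with VST, beside 1.25 and 1.55 with GS alone. In HT-29 it lay 0.61 above, beside 0.70 to 1.53 with GS alone. PPP1R10, a nuclear phosphatase subunit, fell by 4.45 (SE 0.21, adjusted p = 4.64e-07), and VMP1 rose by 3.40 (SE 0.18, adjusted p = 8.38e-07).

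With VST under GS 1639 genes rose and 2527 fell (278 and 4398 with the deposited scaling). Of the ER genes, 0 of 33 measured members rose and 21 fell, or 0 and 25 adjusted over the list alone. For this list the median log2 change was -0.88 (camera adjusted p = 1.03e-05, and adjusted p = 0.662 with an estimated correlation), and -1.32 with the deposited scaling. For the ATF4 list, 0 of 30 measured members rose and 10 fell, or 0 and 10 adjusted over the list alone, with SLC7A5, a leucine transporter, at -1.91. The members had a median log2 change of -0.65 (camera adjusted p = 0.0421, and adjusted p = 0.725 with an estimated correlation), and -1.07 with the deposited scaling. This ATF4 call was lost with the deposited scaling, with the stricter filter, and without HT-29 GS replicate 1 or 2 or HT-29 control 2. Of the cell cycle genes, 25 of 33 measured members rose and 0 fell, or 26 and 0 adjusted over the list alone, with the replication helicase subunits MCM4 and MCM2 at 2.04 and 1.45. The median log2 change was 0.98 (camera adjusted p = 2.89e-08, and adjusted p = 0.544 with an estimated correlation), and 0.56 with the deposited scaling. In the oxidative phosphorylation list, 35 of 45 measured members rose and 0 fell, or 36 and 0 adjusted over the list alone. Its median moved by 0.51 on the log2 scale (camera adjusted p = 4.59e-11, and adjusted p = 0.544 with an estimated correlation), and 0.07 with the deposited scaling. Ribosomal protein genes moved as much here (49 of 51 rose, with a median of 0.51; 0.08 with the deposited scaling, 0.03 with quantile normalization and 0.45 for random lists matched on expression), so the rise was not particular to this list. With 2DG, VST raised 258 genes and lowered 597 (79 and 1280 with the deposited scaling). There HERPUD1 fell by 2.12 (SE 0.54, adjusted p = 0.0372) and ASNS fell by 2.58 (SE 0.48, adjusted p = 0.0128). In its ER list, 0 of 33 measured members rose and 8 fell, or 0 and 12 adjusted over the list alone. The list median was -0.88 (camera adjusted p = 0.00292, and adjusted p = 0.792 with an estimated correlation), and -1.23 with the deposited scaling. In its ATF4 list, 0 of 30 measured members rose and 11 fell, or 0 and 11 adjusted over the list alone. Over the whole list the median log2 change was -0.96 (camera adjusted p = 0.00145, and adjusted p = 0.792 with an estimated correlation), and -1.30 with the deposited scaling. Under GS the count was 2454 without HT-1080 GS replicate 1, which also took the ATF4 median to -0.17 (camera adjusted p = 0.684), and under 2DG it was 179, 211 and 462 without 2DG replicate 1, 2 or 3, with 186, 212 and 461 without their controls.

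The rho0 lines remove the respiratory chain genetically. Without stress, HT-1080 rho0 cells (2 controls against 6) had little signal from mtDNA transcripts. COX1, a complex IV subunit, had a mean signal of 9133 ± 929 (SD, n = 6) in parental and 0.396 ± 0.155 (SD, n = 2) in rho0 controls (adjusted p = 2.65e-17), and ND4 of complex I had 7032 ± 967 and 5.86 ± 7.02 (adjusted p = 3.34e-12). All 7 measured mtDNA transcripts fell, also adjusted over the list alone (camera adjusted p = 1.56e-26, and adjusted p = 0.00764 with an estimated correlation). Their mean rho0 signals, 0.396 to 6.51, lie near or under the added offset of 5.68, so the list median of -9.39 depends on that offset. Among p53 target genes, 9 of 13 measured members rose and 0 fell, or 10 and 0 adjusted over the list alone, with RRM2B, a nucleotide reductase subunit used outside S phase, at 1.76 and the death receptor FAS at 1.78. These genes had a median log2 change of 0.85 (camera adjusted p = 1.81e-06, and adjusted p = 0.0762 with an estimated correlation), and 0.67 with the deposited scaling. Among ATF4 list genes, 8 of 30 measured members rose and 0 fell, or 10 and 0 adjusted over the list alone, with GDF15, a secreted marker of mitochondrial stress, at 1.71. On the log2 scale the median change was 0.38 (camera adjusted p = 0.00304, and adjusted p = 0.812 with an estimated correlation), and 0.21 with the deposited scaling. HSPA5 did not pass the threshold (log2 change -0.13, SE 0.10, adjusted p = 0.472). In all 708 genes rose and 787 fell (356 and 1638 with the deposited scaling, whose all-gene median was -0.15), among them C3, a complement protein, which rose by 4.51 (SE 0.53, adjusted p = 0.000164). Without rho0 control 1 or 2 the count was 420 or 348. In HT-29 the 1 rho0 control against 3 gave 443 genes up and 454 down (252 and 971 with the deposited scaling).

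**Figure D4:**
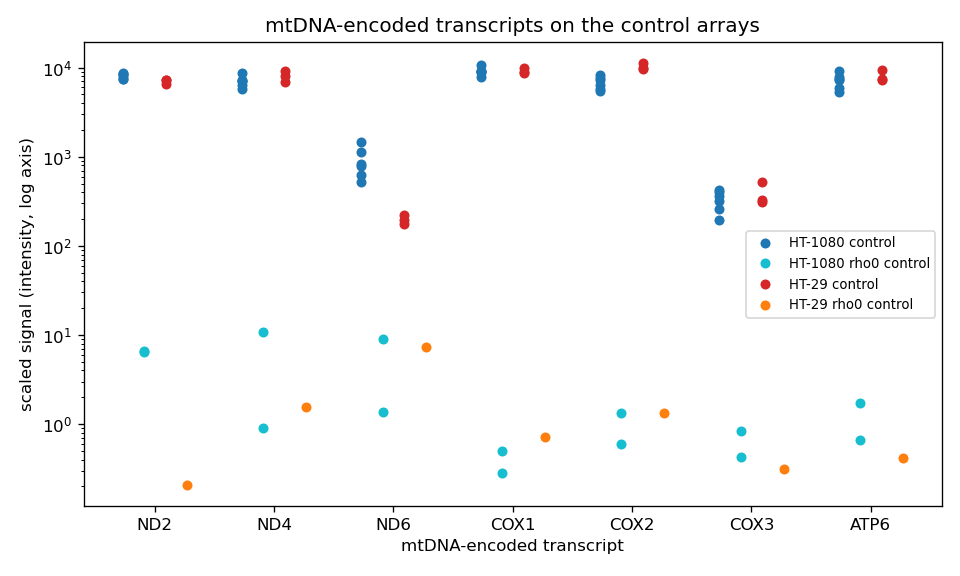
Each point is 1 control array; the vertical axis is the scaled signal (intensity, log axis) of 7 mtDNA-encoded transcripts. Parental HT-1080 and HT-29 arrays have ND2 means of 8119 and 7059, and the rho0 arrays lie at 6.51 (HT-1080, mean) and 0.207 (HT-29).

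Under stress the rho0 cells had 1 array per treatment, and each was set against the parental response. HSP90B1 lay 2.31 above the own control with TM, 0.47 with 2DG and 0.67 with GS (including floating cells). HERPUD1 differed from the parental 2DG response by -3.91 (SE 0.54) and ASNS by -2.98 (SE 0.48). The ASNS signal was already 1508 on the rho0 control, beside 432 to 637 on the controls of the parental 2DG arrays. With 2DG it was 1458 in rho0 and 3635 to 4967 in parental cells. Part of the ASNS difference thus lies in the higher rho0 control. The 2DG response differed from that of parental cells for 783 genes, 191 higher and 592 lower in rho0 (99 and 903 with the deposited scaling), with a median of all genes of -0.10. For the ER list, 0 of 33 measured members rose and 10 fell, or 0 and 17 adjusted over the list alone. For this list the median log2 change was -1.06 (camera adjusted p = 6.11e-06, and adjusted p = 0.668 with an estimated correlation), and -1.31 with the deposited scaling. In the ATF4 list, 1 of 30 measured members rose and 11 fell, or 2 and 15 adjusted over the list alone. The members had a median log2 change of -1.23 (camera adjusted p = 0.000324, and adjusted p = 0.668 with an estimated correlation), and -1.47 with the deposited scaling. The GS response differed for 57 genes up and 114 down in HT-1080 (31 and 465 with the deposited scaling) and 8 up and 2 down in HT-29 (10 and 45), where the rho0 array was taken at 14 h and 2 of the 3 parental arrays at 18 h. The HT-1080 rho0 GS array had an ACTB 3' to 5' ratio of 1.46 (1.18 times its own control) and a polyA to hybridization control ratio 1.80 times that control. The latter ratio lay above both HT-1080 rho0 controls. RNA quality therefore differed there too, by the ACTB ratio. The TM response differed for 0 genes in limma, with 175 at an unadjusted p under 0.05. ER scores were 1.11 with TM, 0.12 with 2DG, 0.10 with GS (-0.16 and -0.29 for 2DG and GS with the deposited scaling) and -0.20 in HT-29 rho0 cells starved for 14 h, beside 0.38 on the parental 14 h array and 1.27 and 1.53 on the 18 h arrays.

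The other preset lists moved less evenly under 2DG with inhibitors. PFKFB4, a regulator of glycolytic flux, fell by 1.18 (SE 0.29, adjusted p = 0.00440), while LDHA, which makes lactate, rose by 0.52 (SE 0.10, adjusted p = 0.000684). In the glycolysis list 8 rose and 1 fell of 21, or 8 and 1 adjusted over the list alone, with a median of 0.18 that was -0.20 with the deposited scaling. In the hypoxia list, with VEGFA at -2.25, 1 rose and 6 fell of 15, or 1 and 7 adjusted over the list alone. HSPD1, the mitochondrial HSP60, rose by 0.68 (SE 0.10, adjusted p = 6.99e-05) and LONP1, a mitochondrial protease, fell by 1.14 (SE 0.17, adjusted p = 9.72e-05). Among mitochondrial chaperones 3 rose and 1 fell of 11, or 5 and 1 adjusted over the list alone, with a median of 0.19 that was -0.20 with the deposited scaling. Random lists matched on expression to the ribosomal protein genes had a median of 0.44 in this comparison, so the rises of LDHA and HSPD1 may not be particular to them. With quantile normalization the list score differences were -0.05 for glycolysis and -0.07 for mitochondrial chaperones. In the p53 list, with TP53INP1 at -3.09 and GADD45A at 2.40, 1 rose and 5 fell of 13, or 1 and 5 adjusted over the list alone. Among autophagy and lysosome genes, 2 rose and 6 fell of 19, or 2 and 7 adjusted over the list alone. For the MondoA list, which holds TXNIP (-2.28) and KLF10 (0.99), 1 rose and 1 fell of 5, or 1 and 2 adjusted over the list alone. Among mesenchymal markers 2 rose and 3 fell of 10, or 3 and 3 adjusted over the list alone, with a median of 0.27 that was -0.12 with the deposited scaling, and among colon epithelial markers 2 rose and 0 fell of 12, or 2 and 0 adjusted over the list alone. In the NRF2 list 2 rose and 2 fell of 15, or 2 and 2 adjusted over the list alone, and in the cholesterol list 3 rose and 3 fell of 16, or 3 and 3 adjusted over the list alone, with a median of 0.25 that was -0.09 with the deposited scaling. Among the synthetases 2 rose and 7 fell of 17, or 2 and 7 adjusted over the list alone, with WARS1 at -2.13.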

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

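The tests of RNA degradation on arrays with a lower signal, of splits that part all pairs or leave the controls unsubtracted, and of a batch shared by the biguanide and VST arrays were chosen after the result was seen, and the list of snoRNA hosts after TAF1D was seen. ASNS, the asparagine synthetase, had a log2 signal of 10.28 on HT-1080 control 6 and 8.77 to 9.33 on the other 5 controls, a gap past Dixon's limit. It was the only one past that limit of 31 values tested in these controls, where chance alone gives about 1 in 20, or 1.55. Control 6 is the reference of the GS replicate 2, GS with Rot or AA, and TM arrays, so their ASNS changes against control start from a high value. It also had the highest signal of the 6 for the ATF4 list as a whole (8.51, the others 7.46 to 7.88) and for CHAC1, TRIB3, ATF4, DDIT3, ATF3 and HERPUD1, none past the limit, so the same holds for that list and these genes.

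The GS effect differed between HT-1080 and HT-29 for 65 genes by a test of the difference itself. The response of MYCT1, a nuclear protein, was 3.58 higher in HT-1080 (adjusted p = 0.0128), and that of DUSP1 -4.54 (adjusted p = 0.0241), both named after their values were seen. The effect of the respiratory inhibitors differed between 2DG and TM for 520 genes, tested the same way, with SLC7A11 and ASNS among those lower under 2DG. Met, Bu and Phen were given with 2DG only, so compounds differ between the sides too. In spike-in controls that no comparison uses, the GS with Rot array that includes floating cells had a polyA to hybridization ratio 2.36 times that of its own control. The largest ratio between 2 controls of 1 line was 2.33, of HT-1080 control 6 over control 4. Control 6 is the own control of that array, so the array lay above every HT-1080 control.

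In a fit of the 3 2DG arrays and 6 controls alone, without the block, 2DG changed 2113 genes. Of 84 splits of these arrays 1, the real one, gave as many, and the highest other gave 114. Each 2DG array shares a set with 1 control, and only 8 splits part all 3 such pairs, too few for a share under 0.05. For the inhibitors with 2DG, tested on differences from the own control, 1 of 56 splits, the real one, reached 4186 genes and the highest other 852. Met, Bu and Phen share control 3, which no 2DG array uses, and Rot and AA share control 4 with 2DG replicate 2, so these differences are not independent. On the signals themselves, without subtracting controls, 1 of 56 splits, the real one, gave 4287 genes and the highest other 499, but the arrays still come from shared sets. That highest other split, in both cases, set the 3 biguanide arrays of control 3 against the other 5, so neither test decides whether chance is excluded. For GS in HT-29, in a fit of those 6 arrays without the block, the 10 splits are too few for a share under 0.05. The real one gave 25 genes and the highest other 1, with 1 as large in all, the real one.

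Arrays of 2DG or GS with a compound had a lower array-wide signal as deposited. This signal is relative to the 100 normalization probe sets, in which the arrays of a line were equal. After the common scaling the hybridization spike-in controls were 1.10 to 1.73 times the own control on these 11 arrays. On the 9 parental arrays of stress alone they were 0.81 to 1.22 times. Spike-ins raised by the scaling go with a fall of the other probe sets, but the ranges overlap. Whether the normalization probe sets rose or the others fell is therefore not settled here. With 2DG, RNA degradation stays open: the highest ACTB 3' to 5' ratio of the 6 arrays was 1.37, beside 1.33 with 2DG alone and 1.42 over all parental arrays of stress alone, and the highest GAPDH ratio was 1.05, beside 1.02 over the latter. With GS and Rot or AA the highest ACTB ratio was 1.76 and the GAPDH ratio 1.07, so it stays open there too. A candidate explanation is the loss of short-lived mRNA, tested on 325 zinc finger genes, of which 18 rose and 106 fell under inhibitors with 2DG. Their median of -0.55 (-0.90 with the deposited scaling, -0.35 with quantile normalization) lay at percentile 0 of random lists matched on expression (median -0.26). With TM it was 0.03. Percentile 0 was also reached by Rot or AA with GS (-0.31), VST with 2DG (-0.55) or GS (-0.46), and rho0 against parental cells with 2DG (-0.48). The rho0 arrays with GS also had a low signal. Against parental cells they gave -0.18 at percentile 0.76 in HT-1080 and -0.03 at 13.72 in HT-29. The mRNA half-lives were not measured.

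Biguanide arrays had higher ER scores than arrays with Rot or AA, by 0.63 against their own controls. An unusual control is argued against, since the gap was 0.61 against the mean of all 6 controls. A batch shared by the biguanide set cannot be told apart from the compounds: the VST array of that set scored 0.13 above the mean of Rot and AA, but VST itself may lower the list. Between the groups HERPUD1 differed by 2.25 (adjusted p = 0.270) and SDF2L1 by 2.65 (adjusted p = 0.0864), neither past the threshold. A biological difference between weak and strong inhibitors stays open, with 0 genes higher and 1 lower in limma and 941 at an unadjusted p under 0.05.

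TAF1D and GAS5, both hosts of small nucleolar RNAs (snoRNAs), rose by 4.69 and 2.83 when Rot or AA was added to GS. Weaker translation-dependent decay of such transcripts could raise them together, so 7 hosts other than TAF1D, GAS5 among them, were tested as a set. Their median was 0.23 at percentile 68.8 of random lists, and 1 rose, which leaves this open. With the deposited scaling the median was -0.15 (all genes -0.39, against -0.03), a shift common to all genes that decides nothing for this set. With VST under GS 6 of 7 rose, at percentile 99.98. The set was already high with GS alone, at percentile 99.95 in HT-1080 (4 rose, 0 fell) and 99.98 in HT-29 (4 rose, 2 fell). It lay at 92.25 for the inhibitors with 2DG and at 86.54 for VST with 2DG.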

How the results depend on the processing

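The alternatives with the deposited scaling, without arrays of high ACTB ratio, for comparisons between biguanides and for scores of single arrays were chosen after seeing the data. Of the single-gene values under the alternatives fixed before the data were examined 9566 counted as the same, 1528 no longer passed, 71 newly passed in the same direction and 1 reversed. A value not past the threshold in the main run that changed direction counted as the same, whether or not it then passed. These 9566 need not all have kept their direction or side of the threshold. The rises of the ER and ATF4 lists with 2DG, GS in HT-1080 and GS in HT-29 kept their direction and, with the preset correlation, their call under each alternative run. With an estimated correlation these calls did not pass (adjusted p = 0.298 with 2DG, 0.284 with GS in HT-1080 and 0.586 in HT-29, for both lists). For all changes listed here the cause was not tested, except that leaving out arrays leaves fewer samples.

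Leaving out 1 array at a time, counts ranged from 92 to 203 for 2DG (950 with all), 20 to 47 for GS in HT-1080 (1076), 1184 to 4199 in HT-29 (3106), 0 to 766 for the difference between lines (65), 1870 to 4000 for inhibitors with 2DG (3929), 217 to 2176 with GS (2820), 35 to 715 for the inhibitor effect under 2DG less that under TM (520; 2DG less TM below), 179 to 462 for 2DG with VST (855), 2454 to 4854 for GS with VST (4166) and 348 to 1447 for rho0 controls (1495). The lowest counts came without 2DG replicate 2, HT-1080 GS replicate 1, HT-29 control 1, HT-1080 GS replicate 2 or control 6 (0 genes in limma, 814 and 812 at an unadjusted p under 0.05), 2DG replicate 2, GS replicate 2, TM with AA, 2DG replicate 1, HT-1080 GS replicate 1 and rho0 control 2, in that order. The ATF4 median for GS with VST ranged from -0.76 to -0.17 (adjusted p from 0.00105 to 0.684) and did not pass without HT-1080 GS replicate 1, HT-29 GS replicate 1 or 2, or HT-29 control 2.

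Without the replicate block the HT-29 GS count was 1857 and that of 2DG with VST 1587. With arrays of the same line only, counts were 2753 (2DG), 2804 (GS), 1159 (HT-29 GS), 2550 (2DG with VST) and 920 (2DG less TM). Without the intensity trend they were 487 (2DG), 444 (GS), 527 (2DG with VST), 155 (2DG less TM) and 0 for the line difference (limma, 1496 at an unadjusted p under 0.05). Offsets of 1% and 20% gave 43 and 122 for the line difference. Without the filter, which tests more genes, 2DG with VST had 517 and 2DG less TM 269. Without arrays of high ACTB ratio GS had 48, 2DG with VST 496 and the line difference 0 (limma, 813 at an unadjusted p under 0.05).

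The deposited scaling gave 1359 genes for 2DG with VST and 990 for 2DG less TM, and quantile normalization 336 for the latter. For GS with VST the ATF4 median was -1.07 (adjusted p = 0.141) with the deposited scaling and -0.65 (adjusted p = 0.0536) with the stricter filter, over a range of p from 0.000663 to 0.141. With biguanides only, 2476 genes changed against 2DG, the ER median was -0.14 (adjusted p = 0.568) and the ATF4 median -0.84 (adjusted p = 0.144). The ER score difference was -0.68 with quantile normalization, -0.61 against all 6 controls and -0.89 with the deposited scaling, each at exact permutation p = 0.0357 (adjusted over 17 lists 0.0607, 0.0552 and 0.0675).

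HK2, a hexokinase, reversed in rho0 controls from -0.89 to 0.72 with the mean of its probe sets, and the transcription factor CREB5 went with inhibitors and 2DG from 2.91 to -1.11 in the run with the deposited scaling, where another of its probe sets stood for the gene (as for 23 genes in all). The deposited scaling reversed ER scores of 0.10 to 0.30 to -0.16 (rho0 2DG), -0.31 (2DG with AA), -0.16 (HT-1080 GS with VST), -0.20 (HT-29 GS with VST), -0.29 (rho0 GS), -0.31 (GS with Rot) and -0.29 (GS with AA). Met against Bu gave 41 genes with quantile normalization. Met against Phen gave 40 with it and 0 with the deposited scaling (limma, 1026 at an unadjusted p under 0.05), and Bu against Phen 5 and 0 (398 at an unadjusted p under 0.05). Not run were the same line only for GS with VST and the line difference, which need both lines, and for rho0, and no block for rho0, which has none. Without arrays of high ACTB ratio no value was left for GS with inhibitors and for 2DG less TM. For TM alone, where no gene passed in the main run, some passed with the deposited scaling and with quantile normalization. Where a signal lies near the added offset its log2 change is compressed, which limits what small changes can be seen.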

Other observations

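The tests of ND6 between lines, of H2AC6 and of H1-2 outside GS with VST were chosen after the result was seen. ND6, the complex I subunit encoded on the light strand of mtDNA, fell by 1.84 with 2DG (adjusted p = 0.000278) and by 1.76 with GS (adjusted p = 0.00234) in HT-1080. In HT-29 its GS change was -0.23 (adjusted p = 0.308), and the lines differed by -1.53 (adjusted p = 0.0276). VST under GS raised it by 1.21 (adjusted p = 0.000516). HT-1080 controls had a mean ND6 signal of 892 ± 353 (SD, n = 6), and HT-29 controls 198 ± 22.4 (SD, n = 3). The median of the 7 mtDNA-encoded transcripts was 0.22 with 2DG and 0.15 with GS.

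Of the histone genes, which were not tested as a group, 3 picked after their values were seen are given. H2AC8, a core histone, changed by 2.77 (adjusted p = 0.00228) with inhibitors and 2DG, 3.49 (adjusted p = 0.00208) with Rot or AA and GS, and 2.81 (adjusted p = 0.00182) with VST and GS. H2AC6, another core histone, was at -0.03 (adjusted p = 0.964), 1.36 (adjusted p = 0.0327) and 2.57 (adjusted p = 0.000113). The linker histone H1-2 changed by 1.72 (adjusted p = 2.72e-05), 1.53 (adjusted p = 0.000441) and 2.35 (adjusted p = 3.84e-06) in the same comparisons, and by -2.06 (adjusted p = 7.93e-05) in unstressed rho0 cells. COL6A3, a chain of microfibrillar collagen, changed by 1.23 (adjusted p = 0.0280) with 2DG, by -2.12 (adjusted p = 0.000292) when inhibitors were added, and by -2.73 (adjusted p = 0.0205) in the inhibitor effect under 2DG less that under TM.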
